A study of Arabidopsis thaliana with 3 samples.

How the data were processed

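Whole seedlings were grown at 22 °C with 16 h of light and 8 h of dark on half-strength medium, and RNA was labelled from 10 ug of total RNA as biotinylated cRNA for Affymetrix arrays, per the labels' protocols. The dye named in the labels, Cy3, does not match that protocol, and the series' design text describes another experiment, on a kinase gene and salt. Groups were therefore taken from the genotype given for each sample: wild type, DRB2 overexpressor and DRB3 overexpressor, with 1 sample per group and 3 arrays in all.

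The deposited values are MAS5 intensities on a linear scale, 1 per probe set and array, made with MAS5 per the submitters' processing notes. The version and target settings are not given in the sources used here. The 2% trimmed mean was 500.05 on each array, so the arrays had been scaled to the same mean and were used as deposited. No detection calls were used here.

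Of 22810 probe sets, 64 control probe sets were left out of the gene comparisons. The gene table listed 14016 probe sets, 13513 with 1 gene and 503 with several, and 8794 were unnamed here. Probe sets with several genes were not used. A gene took its probe set with the highest mean over the 3 arrays, giving 13356 genes, of which 146 had several probe sets. Names were updated through a RefSeq gene table (assembly TAIR10.1), which matched 13286 of them, and no coordinates are given.

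A common floor was set at the mean over arrays of percentile 40 of the non-control probe sets, an intensity of 109. Values under it were set to it before the log2 ratio was taken, so a fold with 1 side at the floor is a lower bound. Genes at least 2-fold apart were counted. With 1 sample per group no test across samples was run, and no p-values are given. A gene list with at least 5 measured members was described by the percentile of its median log2 ratio among 10000 random lists of the same size matched on mean level in 20 bins. This was a description of these arrays. Lists whose random range was 0 to 0 were left out of the list counts in the report. The 24 gene lists, of which 5 had 0 and 4 had at least 5 measured members, the comparisons, the floor, the threshold and the alternatives were chosen before the data were examined. A further 26 lists were made from gene symbols after the probe table was read and before any ratio was computed, since most members of the first lists were unnamed.

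The rule for named genes was as follows. For each overexpressor against wild type it took the 10 largest rises and the 10 largest falls with both values above the floor, and the 3 largest bounds each way. For the DRB3 against the DRB2 overexpressor it took the 5 largest each way. Of each list it took up to 4 members with the largest ratios. psbK, SMZ and ATG3 are named in the report outside this rule, after their values were seen.

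Ratios against the shared wild-type array were set beside 200 simulations of unchanged arrays with 1 shared control and equal noise on each array, and, chosen after seeing the data, 200 with unequal noise. Noise in both was set from the observed ratios, so real differences are part of it. The steps were tested on simulated data with 200 changed genes among 13356. The changed genes were drawn only from those with a mean intensity over 4 times the floor, so recovery of weaker genes was not tested. For the DRB2 overexpressor against wild type, 100% of the 4-fold and 86.2% of the 2.5-fold changes were called in the right direction, with 52 of 13156 unchanged genes called. For the DRB3 overexpressor against wild type the values were 97.6%, 61.1% and 178, and for the DRB3 against the DRB2 overexpressor 100%, 82.4% and 51. Noise in these simulations was taken from the spread between the arrays compared, so real differences are part of it.

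Alternatives were floors at percentile 20 and 60, a pseudocount of 16 with no floor, centring, quantile normalization, a loess correction with a span of 0.3, the mean of a gene's probe sets, and thresholds of 1.5-fold and 3-fold. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.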

Results

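Gene expression was measured in whole seedlings of Arabidopsis thaliana at 2 weeks of age on ATH1 arrays, a short-oligonucleotide platform on which each transcript is read by a set of probes. There were 3 arrays: wild type, a transgenic plant overexpressing DRB2 and a transgenic plant overexpressing DRB3, with 1 array each. DRB genes encode proteins with double-stranded RNA binding domains, a family with known roles in small RNA pathways. There were no replicates, so no difference below carries an error or a p-value, and the number of arrays limits the precision of every value. A gene is said to have risen or fallen where its floored intensities differed at least 2-fold between the arrays compared. A fold with 1 value under the floor of 109 intensity units is a bound, written "at least". The median probe set read 188 intensity units on the wild-type array, 196 on the DRB2 overexpressor array and 187 on the DRB3 overexpressor array. Of 13356 named genes, 7216 were above the floor in wild type, 7405 in the DRB2 overexpressor and 7200 in the DRB3 overexpressor. The probe sets of DRB2, DRB3 and the other family members were not among the named ones, so the level of the overexpressed genes was not analysed here and the labels stand unchecked.

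The comparison of the DRB2 overexpressor with wild type asks which transcripts differ in seedlings with more DRB2. Among rises with both values above the floor, that of AT2G43620 was the largest. This chitinase family gene read 116 in wild type and 748 in the DRB2 overexpressor, 6.44-fold higher. The plant defensin genes PDF1.2b and PDF1.2, markers of jasmonate and ethylene signalling, were 5.83-fold and 4.90-fold higher, PDF1.2b going from 999 to 5824 and PDF1.2 from 623 to 3058. The probe set of PDF1.2b is of a class that can bind related transcripts, so it may read PDF1.2 and the 2 are not separate evidence. AT4G16260, a beta-1,3-glucanase gene, rose 5.21-fold, from 464 to 2415. The largest fall with both values above the floor was that of AT5G20790, from 3452 to 967, and the sucrose-phosphate synthase gene ATSPS4F fell from 4173 to 1532.

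Other rises over wild type in the DRB2 overexpressor were those of AT1G65500 (4.84-fold), AT5G12050 (3.40-fold), the thionin gene AT1G66100 (3.37-fold), the jacalin-related lectin gene JAL23 (3.12-fold), AT4G33720 of the family of pathogenesis-related protein 1 (2.95-fold) and the peroxidase gene AT5G64120 (2.92-fold). For 3 further genes the wild-type value lay under the floor. AT5G39520 read 64.7 in wild type and 1495 in the DRB2 overexpressor, at least 13.8-fold higher. AT4G12490, which encodes a proline-rich lipid transfer-like protein, was at least 6.59-fold higher and the alpha-amylase gene AMY1 at least 2.83-fold higher. Besides AT5G20790 (3.57-fold lower) and ATSPS4F (2.72-fold lower), the falls included AT3G04000 (3.35-fold), AT3G03790 (2.90-fold), AT3G10930 (2.90-fold), AT5G02830 (2.85-fold), AT3G60420 (2.76-fold), AT1G72920, a gene with a TIR domain (2.74-fold), and AT1G64360 (2.58-fold). The other probe set of AT3G60420 lay under the floor on all 3 arrays. AT4G16920, a gene of the TIR-NBS-LRR class of immune receptors, read 1558 in wild type and 101 in the DRB2 overexpressor, at least 14.3-fold lower. AT3G51750 was at least 2.62-fold lower and AT3G43110 at least 2.60-fold lower.

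Genes of the plastid genome were lower as a group on the DRB2 overexpressor array. The median log2 ratio of the 69 measured was -0.33, below all 10000 random lists matched on level, whose central 95% ran from -0.07 to 0.07. Of the 69, 60 had a ratio below 0 and 4 fell at least 2-fold, none rose. The photosystem II genes psbN and psbB fell 2.78-fold and 2.30-fold, and ndhD, for a subunit of the plastid NADH dehydrogenase-like complex, fell 2.16-fold. The control probe set for 25S ribosomal RNA read 12982 in wild type, 3603 in the DRB2 overexpressor and 11339 in the DRB3 overexpressor, and the poly(A) spike-in controls read a median 4.37-fold lower in the DRB2 overexpressor than in wild type and 1.17-fold lower in the DRB3 overexpressor. The hybridisation controls were lower than in wild type in 18 of 18 probe sets on both arrays, a median 1.37-fold and 1.26-fold. Of the lists fixed before the data were examined, the jasmonate response list had 3 measured members, of which PDF1.2 and PDF1.2b rose and THI2.1 read 34.6 in wild type and 160 in the DRB2 overexpressor, a log2 ratio of at least 0.55. Of the 3 measured iron deficiency genes the transcription factor gene BHLH101 rose at least 2.55-fold, while AT3G13610 and PYE had log2 ratios of 0.57 and 0.42. COR15A, a cold-induced gene for a chloroplast-protecting protein, fell 2.06-fold, and the other 3 measured members of its cold, drought and abscisic acid list had ratios under 2-fold. Of 6 auxin response genes, 1 rose, the GH3 family gene WES1 (2.04-fold). None of the 6 measured microRNA and ta-siRNA targets passed 2-fold; their median log2 ratio of -0.11 stood at percentile 12.2 of random lists, with SMZ under the floor on all 3 arrays and taken as 0, and was -0.23 over the other 5. The SNZ transcript went from 195 to 72.0, under the floor, a log2 ratio of -0.84 or lower, and APS4 from 1037 to 1923. AGO7 and SE, the 2 measured genes of the small RNA and DNA methylation machinery, had log2 ratios of at least 0.11, with wild type under the floor, and of -0.14.

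In all, 71 of 13356 genes were at least 2-fold higher and 55 at least 2-fold lower in the DRB2 overexpressor than in wild type, and both values were above the floor for 55 and 48 of them. On simulated arrays 52 of 13156 unchanged genes passed 2-fold in this comparison, with real differences part of the noise. Of 30 lists with at least 5 measured members, 9 had random lists whose central 95% was 0 to 0, since most matched genes lay under the floor, so their percentiles say nothing. Of the other 21, of which chance puts 5% outside the central 95% if genes are independent, 1 stood outside over all members, the plastid-encoded genes. The beta-glucosidase gene BGLU45 rose at least 2.57-fold. With the floor at percentile 20 the counts were 429 higher and 162 lower, so the number and balance of calls rest on where weak signals are cut off.

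**Figure D1:**
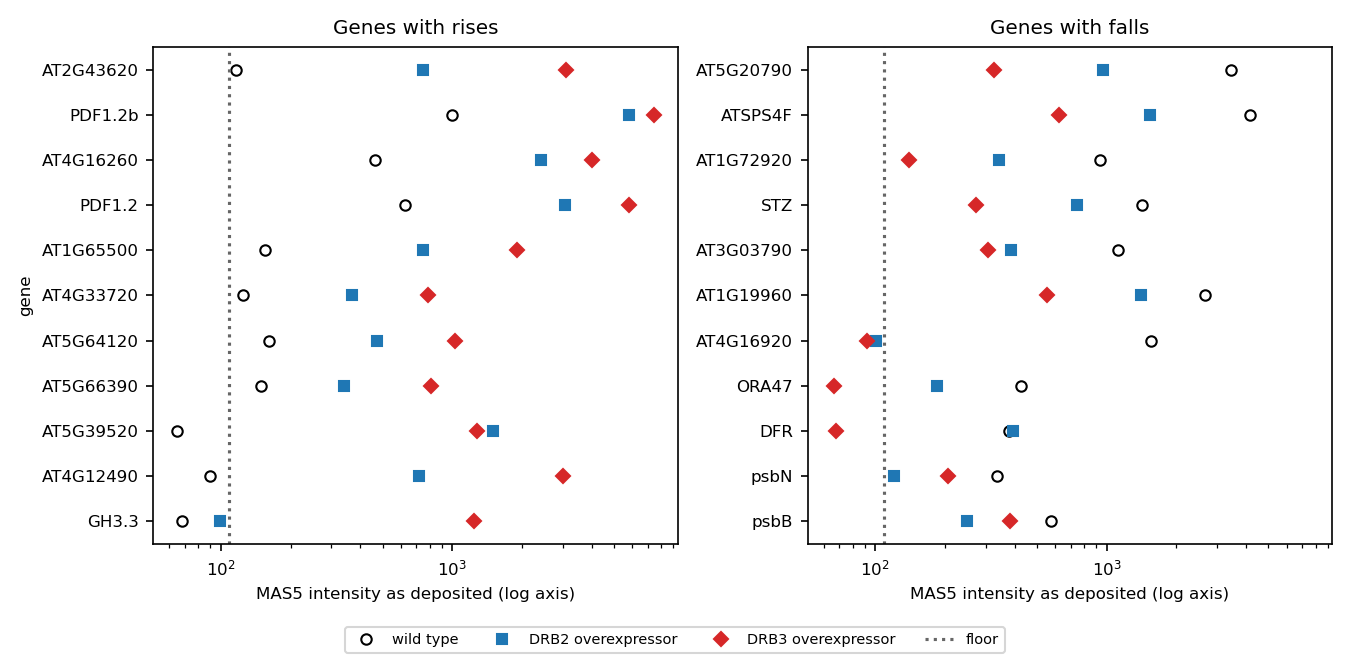
MAS5 intensities (log axis, arbitrary units) of 11 genes with rises and 11 with falls on the wild-type array (open circles), the DRB2 overexpressor array (squares) and the DRB3 overexpressor array (diamonds), 1 array each; the dotted line is the floor. AT2G43620 goes from 116 in wild type to 748 and 3087, and ATSPS4F from 4173 to 1532 and 619.

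The comparison of the DRB3 overexpressor with wild type asks the same of DRB3. AT2G43620 reached 3087, 26.6-fold above wild type, AT1G65500 rose 12.3-fold, PDF1.2 rose 9.31-fold to 5806, AT4G16260 rose 8.61-fold to 3996 and PDF1.2b rose 7.43-fold to 7422. AT4G12490 was at least 27.6-fold higher and AT5G39520 at least 11.8-fold higher. GH3.3, an auxin-induced gene for an enzyme that conjugates auxin to amino acids, lay under the floor in wild type and in the DRB2 overexpressor and read 1235 in the DRB3 overexpressor, at least 11.4-fold higher. AT5G20790 fell 10.5-fold to 327, ATSPS4F fell 6.74-fold to 619, and STZ, a zinc finger repressor gene induced by stress, fell 5.22-fold from 1417 to 271.

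The remaining large rises were those of the peroxidase genes AT5G64120 (6.36-fold) and AT5G66390 (5.41-fold), AT4G33720 (6.33-fold), the cytochrome P450 gene CYP71B23 (5.71-fold) and AT4G39675 (5.69-fold). The remaining large falls were those of AT1G72920 (6.71-fold), AT4G29780 (4.89-fold), AT1G08310 (4.81-fold), AT1G19960 (4.79-fold), AT1G60590 of the pectin lyase-like family (4.03-fold), AT5G42760 (3.94-fold) and AT3G03790 (3.65-fold). Under the floor in the DRB3 overexpressor were AT4G16920, which read 92.2 and was at least 14.3-fold lower, AT4G27657, at least 4.61-fold lower, and ORA47, a gene for an AP2/ERF transcription factor, at least 3.91-fold lower.

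Genes of anthocyanin and flavonoid synthesis were lower in the DRB3 overexpressor. The 5 measured, 1 of them under the floor on all 3 arrays, had a median log2 ratio of -0.88, at percentile 0.06 of random lists, with 1 of the 5 past 2-fold: DFR, for dihydroflavonol reductase, read 377 in wild type and 67.8 in the DRB3 overexpressor, at least 3.47-fold lower. The glycosyltransferase gene UGT78D2 went from 880 to 477 and AT4G14090 from 212 to 42.2. The autophagy list, 9 genes of the ATG8 family of autophagosome proteins and ATG3, was higher, with a median log2 ratio of 0.59 (percentile 99.96) over the 10 genes, of which 9 had a ratio above 0 and 2 passed 2-fold: ATG8H (2.42-fold) and APG8A (2.11-fold). Xyloglucan endotransglucosylase genes, which act on the cell wall, had a median of 0.40 (percentile 99.99) over 10 genes, 3 of them under the floor on all 3 arrays and taken as 0, and one of 0.65 over the other 7; XTH16 and XTH18 rose 3.48-fold and 2.91-fold. Of 6 auxin response genes, GH3.3 and IAA29 (at least 2.37-fold) rose and WES1 had a log2 ratio of 0.99, while the other 3 lay under the floor on all 3 arrays; the median of 0.49 (percentile 100) takes those 3 as 0. Nuclear-encoded photosystem genes had a median of -0.48 (percentile 0.02) over 17 genes, none past 2-fold. The shorter photosynthesis list fixed beforehand, which shares members with it, had a median of -0.10 over 6 genes at percentile 37.3. Plastid-encoded genes had a median of -0.23 (percentile 0.02) over 69 genes with mixed directions, 46 below 0 and 20 above; the photosystem II gene psbA fell 2.48-fold, the only one past 2-fold, and psbK had the highest log2 ratio, 0.64.

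In the jasmonate response list PDF1.2 and PDF1.2b rose and THI2.1 had a log2 ratio of at least 0.55, with wild type under the floor. In the iron deficiency list BHLH101 rose at least 2.20-fold, AT3G13610 rose from 365 to 766 and PYE had a log2 ratio of 0.26. COR47 rose 2.01-fold, COR15A fell 2.66-fold, and COR15B and LTI30 had log2 ratios of 0.64 and 0.12. The clock gene GI rose 2.28-fold, the root hair expansin gene EXPA18 rose 2.39-fold and the other root marker, EXPA7, read 52.1 in wild type and 158 in the DRB3 overexpressor, a log2 ratio of at least 0.54. In the touch and wound list STZ fell and CML38 had a log2 ratio of 0.78. None of the 3 measured salicylic acid genes passed 2-fold on floored values (SAG101, under the floor in wild type, log2 at least 0.90, WRKY53 and GRX480, log2 -0.65 and -0.14), nor did the 3 cell division genes (0.31 for AUR1, 0.02 for AUR2, -0.30 for PRL), the single flowering gene AGL24 (-0.21 or lower, with the DRB3 overexpressor under the floor), BCAT4 of aliphatic glucosinolate synthesis (0.02) or UGT74B1 of indole glucosinolate synthesis (-0.30). The 6 microRNA and ta-siRNA targets had a median of -0.13 at percentile 15.2, and of -0.25 over the 5 above the floor on at least 1 array. The 3 measured reference genes AT4G34270, PEX4 and AT2G28390 had log2 ratios of -0.32, 0.26 and -0.07.

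In all, 192 genes were at least 2-fold higher and 205 at least 2-fold lower in the DRB3 overexpressor than in wild type, 397 genes or 2.97%. On simulated arrays 178 of 13156 unchanged genes passed 2-fold in this comparison, with real differences part of the noise. Of 20 lists whose random range was not 0 to 0, 6 stood outside the central 95% of random lists, where chance puts 5% if genes are independent. Genes of a family may move together between 2 single arrays, and some lists share members, so an excess over 5% is no measure of an effect. With the floor at percentile 60 the counts were 98 and 107, and the flavonoid, auxin, xyloglucan and nuclear photosystem lists were then inside the random range. The ratio of 3' to 5' signal of the GAPDH control was 9.31 in wild type, 5.77 in the DRB2 overexpressor and 3.89 in the DRB3 overexpressor, and that of the Actin control 13.0, 6.45 and 5.01. The ratios of the other GAPDH pair were 2.42, 2.11 and 1.5, and those of the ubiquitin control 2.80, 2.47 and 2.01. In a further Actin pair the 3' probe set read 6722, 5764 and 7464 in the same order and the 5' probe set 230, 233 and 421. In a further ubiquitin pair they read 17072.5, 16319.4 and 19402.5, and 3664, 3541 and 4985. In both pairs the 5' reading of the DRB2 overexpressor was close to that of wild type.

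**Figure D2:**
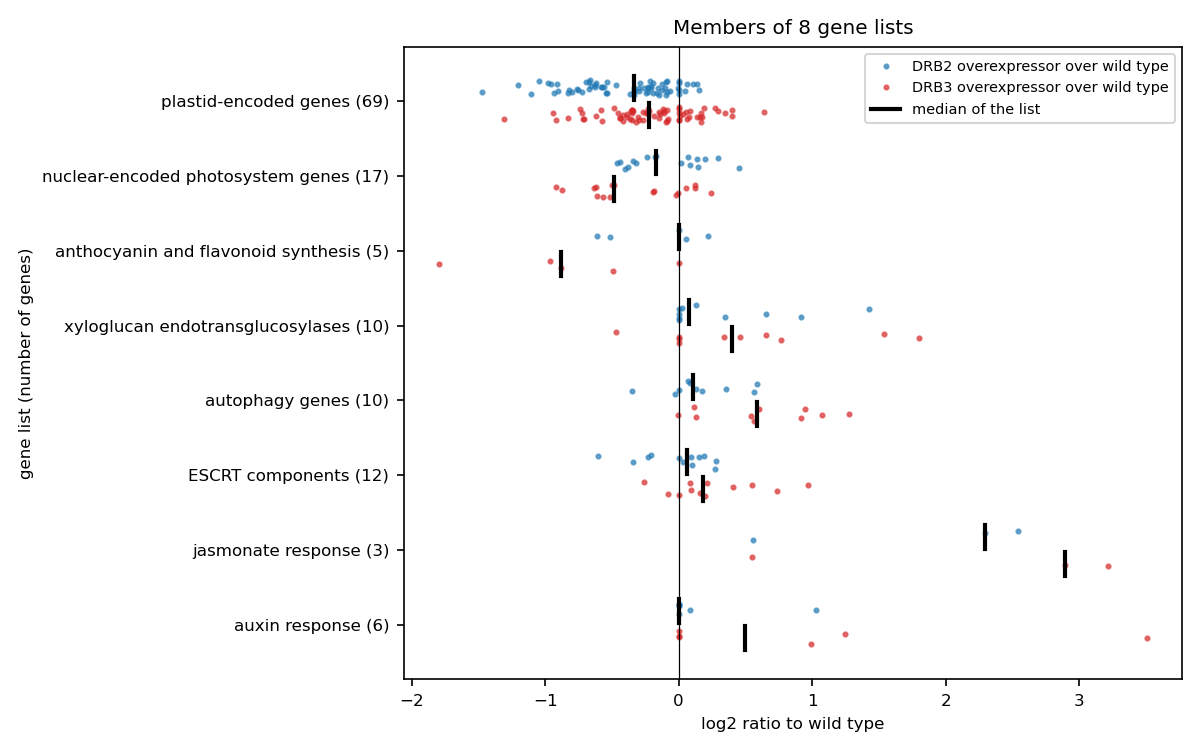
Log2 ratios to wild type of the members of 8 gene lists (points, 1 per gene) in the DRB2 overexpressor (blue) and the DRB3 overexpressor (red), 1 array each; black bars are list medians and the number of genes is in brackets. The 69 plastid-encoded genes have medians of -0.33 and -0.23, and the 10 autophagy genes 0.11 and 0.59.

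The direct comparison of the overexpressors shows where they part. The largest rises in the DRB3 over the DRB2 overexpressor with both values above the floor were those of AT5G48570, an immunophilin gene induced by heat (5.76-fold, from 119 to 687), AT1G43910 (4.36-fold), AT5G12110, for a subunit of elongation factor 1 (4.26-fold), AT4G12500 (from 146 to 611) and AT4G12490 (4.18-fold). The largest falls were those of AT5G48490, for a lipid transfer protein (5.38-fold, from 5004 to 931), AT3G63340 (4.99-fold), AT4G12980 (3.63-fold), AT4G02850 (3.18-fold) and AT1G08310 (3.11-fold). Autophagy genes had a median log2 ratio of 0.54, above all 10000 random lists, and genes of the ESCRT complexes, which sort membrane proteins for degradation, one of 0.28 (percentile 99.4) with 10 of 12 above 0 and none past 2-fold. Plastid-encoded genes had a median of 0.21, above all random lists, psbK rising and psbA falling. Xyloglucan endotransglucosylases had a median of 0.15 (percentile 99.1), or 0.37 over the 7 above the floor on at least 1 array, with no gene past 2-fold. Photosynthesis genes had a median of -0.33 (percentile 2.31), nuclear-encoded photosystem genes one of -0.21 (percentile 2.29) and flavonoid genes one of -0.37 (percentile 2.47), each close to the limit of 2.5, and of these genes DFR fell at least 3.61-fold. In all, 77 genes were at least 2-fold higher and 82 at least 2-fold lower, and on simulated arrays 51 of 13156 unchanged genes passed 2-fold, with real differences part of the noise. Of 21 lists whose random range was not 0 to 0, 7 stood outside it, where chance puts 5% if genes are independent. The photosynthesis and the photosystem list were inside the random range after quantile normalization and after loess, and the flavonoid and xyloglucan lists with the floor at percentile 60.

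Across both comparisons with wild type, 49 genes rose in both overexpressors and 34 fell in both, among them PDF1.2, PDF1.2b, AT4G16260, AT4G33720 and both peroxidase genes on the higher side and AT5G20790, ATSPS4F, AT1G72920 and AT4G16920 on the lower side. Both comparisons use the same wild-type array, and simulated unchanged arrays against 1 shared control gave 14.9 and 21.8 genes, while independent lists of these sizes among the 13356 genes would share 1.02 and 0.84. Across the 7766 genes above the floor on at least 1 array the log2 ratios correlated with a Pearson r of 0.64, where the simulation gave 0.50, and their covariance was 0.122 against a simulated 0.0776; genes are not independent replicates. That simulation gave each array the same noise, taken from the DRB3 to DRB2 overexpressor ratios. Real differences between the overexpressors are therefore part of its noise. The variance of the DRB3 to wild type ratios was 0.256 where it gave 0.155 (0.149 to 0.162). A simulation chosen after seeing the data, with the noise of each array set to match the 3 variances, gave the observed correlation and covariance by construction, 37.2 genes higher in both (95% of simulations from 26 to 48.0) and 43.0 lower in both (30 to 55). It missed other values: 67.4% of genes had the same sign in both comparisons where it gave 71.4% (70.5% to 72.4%), and the DRB2 overexpressor lay between the other arrays for 40.7% of all genes where it gave 44.8% (43.8% to 45.7%). The simulation with equal noise gave 32.8% (31.7% to 33.7%) in between, further from the 40.7% here. Simulated values were not floored as the data were. For 3.39% of genes the DRB2 overexpressor was tied with another array, where unequal noise gave 0, so these shares are not fully comparable. The single wild-type array cannot be split, so part or all of the excess can come from that shared array, and how much is not known. The DRB2 overexpressor lay between wild type and the DRB3 overexpressor for 161 of the 192 genes that rose in the latter (83.9%) and 183 of the 205 that fell (89.3%). Picking genes by that ratio favours this order, and the simulated unchanged arrays gave 75.2% (95% of simulations from 65.7% to 83.3%) and 75.6% (66.7% to 83.6%) with equal noise, and 84.2% (79.0% to 89.4%) and 84.1% (78.6% to 88.8%) with unequal noise. The unequal noise variances were 0.122 for the wild-type array, 0.0211 for the DRB2 overexpressor array and 0.134 for the DRB3 overexpressor array. They were set from the observed ratios, so a high share in between is largely built in.

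**Figure D3:**
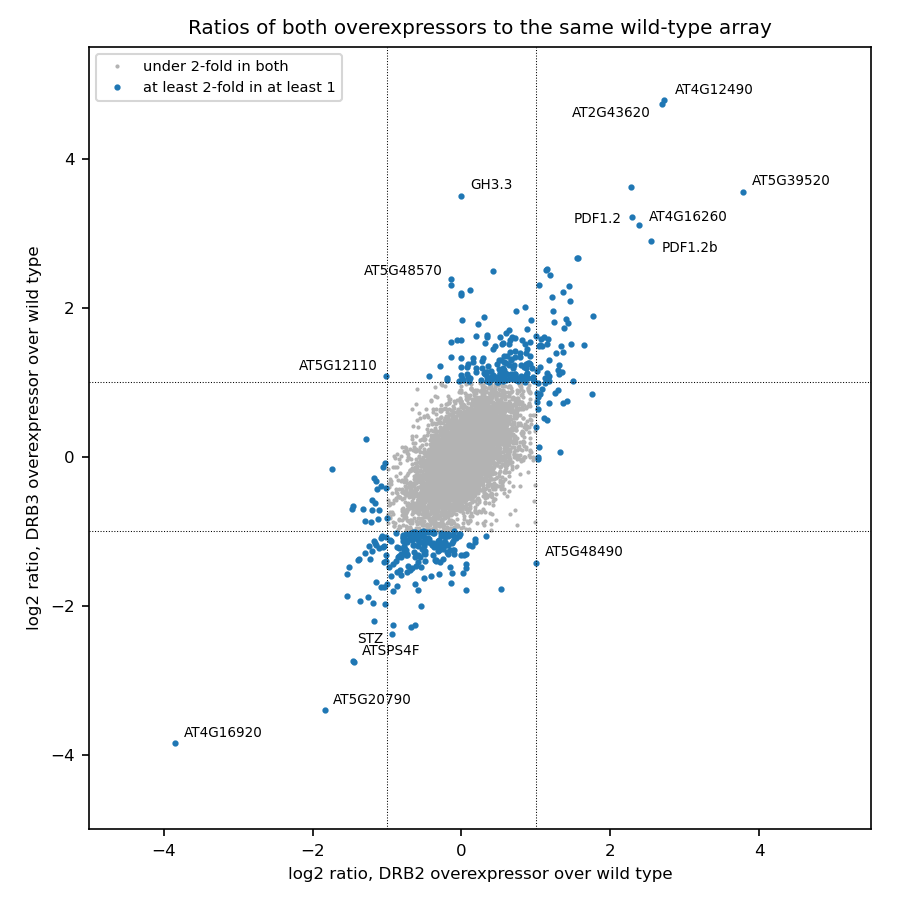
Log2 ratio to wild type in the DRB2 overexpressor (horizontal) and the DRB3 overexpressor (vertical) for the 7766 genes above the floor on at least 1 of the 3 arrays; blue points passed 2-fold (dotted lines) in at least 1 comparison. 49 genes lie past 2-fold higher in both and 34 past 2-fold lower in both, and AT5G48490 and AT5G12110 lie on opposite sides.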

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

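The tests of RNA ends on the genes that fell and on those that rose, and the simulated shares of genes in between, were chosen after the result was seen; the other tests were written down before their values were seen.

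AT5G48490 was higher in the DRB2 overexpressor and lower in the DRB3 overexpressor than in wild type (2496, 5004 and 931 in wild type, DRB2 and DRB3 overexpressor), a log2 ratio of -2.43 between the overexpressors, and this difference was not tested. AT5G12110 went the other way (594, 295 and 1258), a log2 ratio of 2.09, also not tested. In the DRB2 overexpressor both genes only just passed the threshold against wild type, AT5G48490 at 2.00-fold higher and AT5G12110 at 2.01-fold lower.

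Among the 8730 unnamed probe sets, outside the gene comparisons, 78 were at least 2-fold higher in the DRB2 overexpressor than in wild type and 199 in the DRB3 overexpressor. The probe set with the largest rise in the DRB2 overexpressor read 285 in wild type, 3259 in the DRB2 overexpressor and 245 in the DRB3 overexpressor. The one with the largest rise in the DRB3 overexpressor read 192, 123 and 10141 in the same order. The sources used here do not pair these 2 probe sets with genes. Among control probe sets, the 6 5' controls read 2.48-fold and 1.87-fold (GAPDH), 2.69-fold and 1.83-fold (Actin) and 1.36-fold and 1.35-fold (ubiquitin) higher in the DRB3 overexpressor than in wild type.

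The DRB3 overexpressor differed from wild type with the DRB2 overexpressor in between for most of its changed genes, and the 3' to 5' ratios of the control transcripts fell in the same order of arrays. The 5' readings themselves were close in wild type and the DRB2 overexpressor for an Actin control (230 and 233). The same held for the ubiquitin controls (3664 and 3541, 6147 and 6297). Those of the GAPDH controls and the other Actin control were higher in the DRB2 overexpressor. Noise of single probe sets as the only source of the ratios is argued against for 26 genes with several probe sets. Their DRB3 to wild type ratios correlated at 0.62 (95% bootstrap interval over genes 0.357 to 0.791). These genes were not picked for being changed, and 7.69% of them had ratios at least 2-fold apart. Most genes had 1 probe set, so how much noise enters the changed genes is not known. Picking genes by their DRB3 to wild type ratio favours the in-between order, by an amount that depends on the noise assumed. The order held for 83.9% of the risen and 89.3% of the fallen genes here. Simulated unchanged arrays gave 75.2% and 75.6% with equal noise on each array, which the variances of the ratios do not match. With unequal noise they gave 84.2% and 84.1%. That noise was set from the observed variances and is least on the DRB2 overexpressor array, so these shares are largely built in. Both missed the share of all genes in between, 40.7% here, 32.8% with equal and 44.8% with unequal noise. Unequal noise also gave the same sign in both comparisons for 71.4% of genes, and 67.4% here, but simulated values were not floored as the data were. Better preserved 5' ends on the DRB3 overexpressor array cannot be told apart from other causes for either direction: the fallen genes lay below the lowest 3' control (a log2 difference of -1.18) because they were picked for being low, and that 36.5% of the risen genes exceeded every 5' control rests on only 6 controls. An effect of the transgenes, or of growth and harvest of single samples, also stays open and was not tested.

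Plastid-encoded genes were lower on both overexpressor arrays. A trend of the ratio with signal level is argued against, since the group stood below random lists matched on level. After a loess correction it stood at percentile 0 and 0.195. As the lists were already matched on level, the correction adds little separate evidence. Less carry-over of RNA without a long poly(A) tail cannot be told apart from a change in the plants on either array. Of 16 mitochondrially encoded genes only 7 were above the floor on the arrays, too few for a result against it. The median over all 16 was held at 0 by the genes without a ratio, so it could not come out for less carry-over. Over the 7 the median log2 ratios were -0.20 in the DRB2 overexpressor and -0.22 in the DRB3 overexpressor (95% bootstrap intervals over genes -0.53 to -0.07 and -0.70 to -0.10). Both medians lay below the bounds written beforehand for less carry-over, -0.17 and -0.11, but the intervals reach above these bounds. The intervals give the spread between genes on single arrays and no error between samples. The 25S ribosomal RNA control was lower on the DRB2 overexpressor array (3603, and 12982 in wild type) but little lower on the DRB3 overexpressor array (11339), and the polyadenylated spike-ins, which such carry-over leaves alone, were also lower on the DRB2 overexpressor array (median 4.37-fold, 24 of 24).

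AT4G16920 was under the floor on both overexpressor arrays and at 1558 in wild type. Loss of a chromosome segment in the transgenic lines cannot be told apart from lower expression, since only 1 named neighbour within 5 annotated genes on each side was above the floor in wild type (AT4G16880, at 114 in wild type, 128 in the DRB2 overexpressor and 88.2 in the DRB3 overexpressor). A sequence difference between the seed stocks that weakens hybridisation was not tested.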

How the results depend on the processing

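The counts over all non-control probe sets, over genes above the floor on both arrays and without organelle genes, the list medians over members above the floor, and the simulation with unequal noise, were chosen after seeing the data; the other settings were planned. No paired analysis was possible because each group had 1 sample, and for the same reason no replicate could be left out. No named gene ratio past 2-fold changed sign. The balance of calls between the overexpressors, 77 higher and 82 lower, turned to more higher than lower with quantile normalization (84 and 77), loess (80 and 78), the floor at percentile 60 and the 3-fold threshold, so it has no settled direction, and that of the DRB3 overexpressor against wild type turned at 3-fold. Centring, quantile normalization, loess, the mean of probe sets and leaving out organelle genes kept every count within 1.5 times its value. Counts below are given as higher and lower for the DRB2 overexpressor against wild type, the DRB3 overexpressor against wild type and the DRB3 against the DRB2 overexpressor, then shared by both overexpressors; reported values were 71 and 55, 192 and 205, 77 and 82, then 49 and 34. With the floor at percentile 20 they were 429 and 162, 369 and 400, 164 and 404, then 133 and 82, with a correlation of 0.575 for the ratios. At percentile 60 they were 29 and 24, 98 and 107, 32 and 30, then 20 and 14, with a correlation of 0.658. With a pseudocount of 16 and no floor they were 662 and 279, 508 and 512, 261 and 610, then 207 and 112. At 3-fold they were 10 and 3, 48 and 30, 13 and 8, then 8 and 2. At 1.5-fold they were 453 and 390, 710 and 747, 389 and 510, then 232 and 221. Over all non-control probe sets they were 154 and 136, 399 and 435, 144 and 178, then 107 and 86, since more features were counted. The other shifts follow from how many weak or small ratios each setting admits. The low floor and the pseudocount admit weak signals, which on the DRB2 overexpressor array were more often higher, so the balance of its calls depends on them. Of 147 named gene ratios past 2-fold, 65 fell under 2-fold in at least 1 alternative. Of 15 list comparisons outside the random range, 1 of them (beta-glucosidases, 0 to 0) with a range that carries no information, 6 stayed outside in each of the 7 settings planned for lists: the plastid-encoded genes in all 3 comparisons, the autophagy genes in the DRB3 overexpressor against each other array, and the ESCRT genes. With members above the floor only, 19 of 84 list comparisons stood outside, where chance gives 4.2 if genes are independent. The 3 comparisons share arrays, so a list outside in several of them is not separate evidence. Signal over background limits the 5590 genes under the floor on all arrays, for which no ratio is known.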

Other observations

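The medians over members above the floor were chosen after the results were seen. Plant defensins and related small cysteine-rich peptides did not stand apart over all 15 members, 6 of them under the floor on all 3 arrays, with a median log2 ratio of 0 in both comparisons with wild type (percentiles 48.2 and 51.5). Over the 9 above the floor on at least 1 array, 5 had a ratio above 0 and 4 below, and the medians were 0.53 in the DRB2 overexpressor (percentile 99.98) and 0.36 in the DRB3 overexpressor (percentile 99.4). In each, 3 genes rose: PDF1.2, PDF1.2b, whose probe set may read PDF1.2, and PDF1.4, the last at 32.3 in wild type, under the floor, and at 281 and 359 in the overexpressors. Tetraspanins, a family of membrane proteins, had a median of 0 over all 15 members, where random lists also gave 0 to 0, and of 0.38 and 0.40 over the 7 above the floor (percentiles 99.8 and 99.6), with no member past 2-fold. Over members above the floor, the DRB2 overexpressor also had medians outside the random range for the beta-glucosidases (0.29, percentile 99.2, 11 of 12 above 0) and the xyloglucan endotransglucosylases (0.35, percentile 98.6, 7 genes). In the DRB3 against the DRB2 overexpressor the expansins (-0.29, percentile 1.42, 12 genes) and the serine carboxypeptidase-like genes (-0.22, percentile 0.775, 15 genes) were outside only with this choice. It lets genes in through the array on which they are high. THI2.2, another small peptide gene, read 172 in wild type and 61.1 and 56.6 in the overexpressors.

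The expansin-like genes went opposite ways in the DRB3 overexpressor, EXLA1 rising 2.99-fold and EXLB1 falling 2.94-fold. TBL26 of the family that acetylates wall polysaccharides fell 2.55-fold, and the glycosyl hydrolase gene GH9B8 fell 2.01-fold. Among UDP-glycosyltransferases, UGT72E1, UGT85A2 and UGT76B1 rose 2.28-fold, 2.18-fold and 2.14-fold in the DRB3 overexpressor and the flavonol glycosyltransferase gene UGT78D1 fell 2.05-fold. The sugar transporter gene SWEET1 rose 2.08-fold in the DRB2 overexpressor. Serine carboxypeptidase-like genes scpl20 and scpl46 fell 2.86-fold and 2.04-fold in the DRB3 overexpressor, and the ubiquitin ligase gene PUB26 fell from 441 to 210.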
